A study of Homo sapiens with 4 samples.

How the data were processed

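Total RNA from SK-MEL-2, an established human melanoma cell line, was hybridised to 4 one-colour oligonucleotide arrays. Per the labels, 2 arrays came from cells given an adenovirus carrying LacZ, the control gene, and 2 from cells given an adenovirus carrying E2F-1, and each pair of titles bears a repeat number. The labels do not say what arrays of one repeat shared, nor whether the arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

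The deposited table gives 1 intensity per probe set and array on a linear scale, for 12625 probe sets, without detection calls. The software and settings the authors used for these intensities are not given in the sources used here. From the values, each deposited array had a 2%-trimmed mean intensity of 250.1, which is the form of a table already scaled array by array. Array medians were 105.6 and 98 in repeat 1 (LacZ and E2F-1) and 78 and 82.6 in repeat 2.

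Each array was scaled to a 2%-trimmed mean of 250, which moved the deposited values by under 0.1%. Scaled values under the 20th percentile of all values, 18.4, were set to that floor, and log2 was taken. The 67 control probe sets were left out, and 7535 probe sets were kept whose mean over the 4 arrays reached the 40th percentile of such means, 61.4. A value at the floor has no measured size, so a difference against a group with both arrays at the floor is written as a lower bound.

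Probe sets were named through a platform annotation table that can be old. Of the probe sets, 10961 had 1 gene symbol, 545 had several and 1119 had none, and those with several were not named. Gene identifiers matched 10949 of the single-symbol probe sets to current RefSeq gene records, which changed 0 symbols. A gene was represented by its kept probe set with the highest mean over the 4 arrays, which gave 5506 genes, and other probe sets of a named gene that differed in sign are mentioned.

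E2F-1 was compared with LacZ by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) with Benjamini-Hochberg adjustment over the 7535 probe sets and a threshold of 0.05. This test had 2 residual degrees of freedom, and 5.24 with those its prior added. A blocked limma fit with the repeat number as a term, one of the alternatives set in advance, was computed as well. It had 1 residual degree of freedom, and 7.96 with its prior. A count that needs no variance estimate was also made: probe sets whose lowest E2F-1 array was at least 2-fold above the highest LacZ array, or whose highest E2F-1 array was at least 2-fold below the lowest LacZ array. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so none was used.

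The tests were run on simulated data of the same size, with 100 probe sets changed 2-fold and 100 changed 4-fold in each of 20 simulations of E2F-1 against LacZ on 7535 probe sets. The fit without the block recovered 0 of the 100 at either size. The blocked fit recovered on average 61.8 of the 100 changed 2-fold and 95.4 of the 100 changed 4-fold, and 11.2% of its calls were false, above the nominal rate. The simulated noise was normal, independent between probe sets, and had the spread estimated by the blocked fit itself. The share of false calls on the real arrays, where probe sets can vary together, is therefore not known. The gene list test recovered 1 of 1 shifted list and called 0 of 20 unshifted lists. The simulated genes varied independently, so this does not show its rate of false calls for lists whose genes vary together.

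There were 26 gene lists, written from textbook knowledge. The design, the lists, the rule for named genes and the alternatives were set before the data were examined. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists tested. Camera with an estimated correlation and limma's fry were run beside it. With an estimated correlation, camera takes its p from the residual degrees of freedom, 2 without the block and 1 with it. That form of camera therefore has little power here. Camera sets a list against all other genes, and fry asks whether its genes move on balance one way.

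The rule named E2F1 and MAP3K5, a keyword of the labels under its name ASK-1. It named the 12 genes with the largest positive and the 12 with the largest negative difference among those past the limma test. As 0 passed, it took them from the genes 2-fold apart in every comparison of an E2F-1 with a LacZ array. It named up to 4 members per list, by size among those past the test and otherwise by the smallest limma p without the block. Other members are named where they complete a count or were chosen after their values were seen.

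The alternatives covered the scaling (none, quantile, median), the floor, the filter on dim probe sets, the intensity trend, the block, the fold and p thresholds, the list test, and each array left out in turn. Alternatives chosen after seeing the data combined the block with each of these choices, used each repeat alone, or left out the probe sets brightest in repeat 2. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.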

Results

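SK-MEL-2 melanoma cells received an adenovirus carrying either E2F-1, a transcription factor that drives entry into S phase and can also start apoptosis, or LacZ, a bacterial gene that serves as the vector control. Transcript levels were read on 2 arrays per group, 1 of each group in repeat 1 and 1 of each in repeat 2. The comparison asks which transcripts differ in melanoma cells after transfer of E2F-1. Values are scaled probe-set intensities in arbitrary units, and differences are E2F-1 minus LacZ on the log2 scale with the standard error (SE) of the limma fit without the block, at 2 arrays per group. The SE is that of this fit also where an adjusted p of the blocked fit stands beside it.

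The probe sets for the transferred gene itself differed little between the groups. The brighter E2F1 probe set read 224 and 163 in the LacZ arrays of repeats 1 and 2, against 208 and 192 in the E2F-1 arrays, a difference of 0.06 ± 0.36 (limma adjusted p = 0.998, and 0.892 with the repeat as a block). The dimmer one read 62.8 and 45.9 against 86.0 and 76.3, a difference of 0.59. Whether these probes lie in the part of E2F1 carried by the vector is not given in the sources used here. They therefore cannot be used to check the labels, and whether they measure the transferred transcript is open. Without the LacZ array of repeat 2 the sign of the first difference turned, to -0.17.

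In the E2F-1 cells, 161 probe sets read at least 2-fold above both LacZ arrays in both E2F-1 arrays, and 60 read at least 2-fold below in the same sense. With 1 probe set per gene these were 120 genes higher and 52 lower. The genes with the largest positive differences included both E-type cyclins (CCNE1 and CCNE2), the transcription factor MYB, the receptor tyrosine kinase FGFR3 and the activin-binding protein follistatin (FST). Those with the largest negative differences included the kinase MAP2K5, the matricellular growth factor CCN2, the transcription factor IRF4 and the small GTPase RHOB.

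The spread between repeats was wide against these differences. The other split that mixes groups and repeats gave 7 probe sets 2-fold apart in every comparison, whereas the split by repeat gave 754, so arrays differed more by repeat than by vector. The limma test without the block called 0 probe sets higher and 0 lower, with a smallest adjusted p of 0.313, while 300 and 194 had an unadjusted p under 0.05. With the repeat as a block, limma called 360 higher and 258 lower, and these calls included 147 of the 161 and 48 of the 60. The blocked fit made 0 calls without the filter on dim probe sets or without the intensity trend. With quantile normalization it called 197 higher and 74 lower, so that higher ones made up 72.7% of its calls in place of 58.3%.

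Within repeat 1, 606 probe sets were at least 2-fold higher and 693 at least 2-fold lower in E2F-1. Within repeat 2 these were 546 and 307, and 264 and 148 met the limit in both. Only 26 were 2-fold one way in repeat 1 and 2-fold the other way in repeat 2. Across the 7535 probe sets, which are not independent replicates, the differences of the 2 repeats had a Pearson correlation of 0.53 and a Spearman correlation of 0.52, and 68.8% had the same sign. Bright probe sets lacked this agreement. The Pearson correlation was 0.04 over the 237 with a mean of 3200 or more in repeat 2, and 0.56 over the others. Leaving out 1 array lowers the number of comparisons and raised the 2-fold counts, to 446 and 124 without the LacZ array of repeat 1, 245 and 223 without E2F-1 of repeat 1, 355 and 290 without LacZ of repeat 2, and 385 and 402 without E2F-1 of repeat 2.

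**Figure D1:**
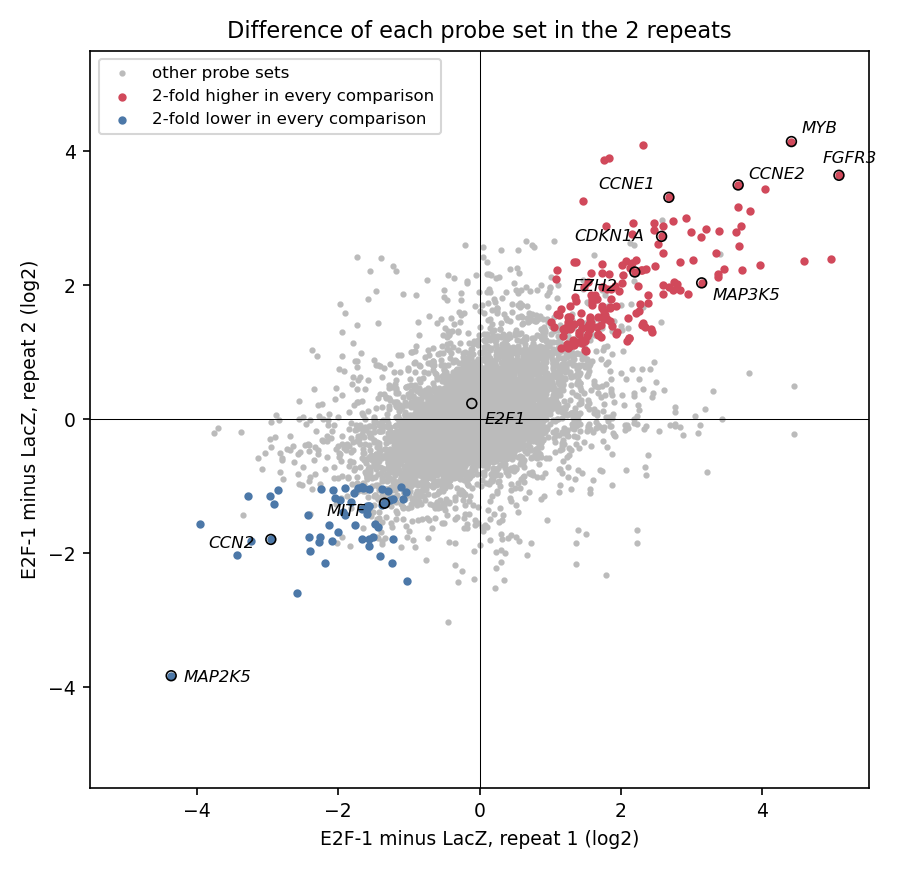
Each point is 1 of 7535 probe sets, with its E2F-1 minus LacZ difference (log2) in repeat 1 on the horizontal axis and in repeat 2 on the vertical axis. The 161 probe sets 2-fold higher and the 60 2-fold lower in every comparison are coloured, and ringed points mark some of the genes named in the text, with CCNE2 at 3.66 and 3.50 and MAP2K5 at -4.36 and -3.83.

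Among the genes with higher readings, FGFR3 went from 10.1 and 35.3 in the LacZ arrays to 623 and 440 in the E2F-1 arrays of repeats 1 and 2, a difference of 4.36 ± 0.53 (blocked adjusted p = 0.00148). MYB read 25.6 and 52.0 against 544 and 919, a difference of 4.28 ± 0.53 (blocked adjusted p = 0.000342), and 6 other MYB probe sets had the same sign, at 0.55 to 2.87, while 1 more was at the floor on 3 arrays. CCNE2, a cyclin that activates CDK2 at the start of S phase, read 112 and 74.4 against 1406 and 840, a difference of 3.58 ± 0.41 (blocked adjusted p = 0.000286). Its relative CCNE1 read 151 and 96.4 against 966 and 957, a difference of 2.99 ± 0.35 (blocked adjusted p = 0.000665). FST read 137 and 134 against 1204 and 884, a difference of 2.93 ± 0.32, and the imprinted gene PEG10 read 190 and 210 against 1507 and 1464, a difference of 2.89 ± 0.28.

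The probe sets that represent the activin subunit INHBB and the LIM-homeodomain factor LHX2 were at the floor in both LacZ arrays. With E2F-1, INHBB read 440 and 94.96, a geometric mean 11.1-fold above the floor of 18.4, and LHX2 read 286 and 90.5, with a mean 8.75-fold above it. A dim second LHX2 probe set, at the floor in the LacZ array of repeat 2 only, differed by 0.84. The other genes among the 12 were the lysophospholipid acyltransferase LPCAT4 (3.42), LZTS3 (3.29), the synaptic vesicle protein SYNGR3 (3.20) and F3, which encodes tissue factor (3.02). For LPCAT4, LZTS3, SYNGR3 and FGFR3, 1 of the LacZ arrays was at the floor. The sizes and their order depend on the floor. With it at the 5th percentile FGFR3 differed by 4.79, INHBB by 4.55, LHX2 by 4.22, LZTS3 by 4.12 and LPCAT4 by 3.45, while MYB and F3 kept their values. With it at the 40th percentile both LacZ arrays were at the floor for 7 of these genes, so the differences were at least 1.85 for INHBB, 1.5 for LHX2, 1.77 for LZTS3, 2.11 for LPCAT4, 2.14 for F3, 3.20 for FGFR3 and 3.64 for MYB, and SYNGR3, with 1 such array, differed by 2.39. All 12 passed the blocked test, with adjusted p between 0.000286 and 0.0192, and none passed without the block, where the smallest adjusted p was 0.313.

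MAP2K5, the kinase upstream of ERK5, had the largest negative difference. Its brightest probe set read 2151 and 5660 in the LacZ arrays against 105 and 399 with E2F-1, a difference of -4.09 ± 0.79 (blocked adjusted p = 0.000286). The 4 other MAP2K5 probe sets gave differences between -0.40 and 0.58, at LacZ readings of 61.2 to 146, near the LacZ array medians of 105.6 and 78. CCN2 read 1382 and 784 against 179 and 226, a difference of -2.37 ± 0.39 (blocked adjusted p = 0.00349). IRF4 read 575 and 398 against 108 and 117, a difference of -2.08 ± 0.35 (blocked adjusted p = 0.00349), and 2 dim IRF4 probe sets were at the floor in both E2F-1 arrays and at least 1 LacZ array. SLC26A2, a sulfate transporter, read 1013 and 663 against 210 and 187, a difference of -2.05 ± 0.34 (blocked adjusted p = 0.00186).

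The remaining genes with large negative differences were ZCCHC24 (-2.73), PLEKHO2 (-2.59), the cAMP-activated exchange factor RAPGEF3 (-2.52), the ubiquitin ligase RNF41 (-2.20), the sulfotransferase TPST1 (-2.18), the zeta-globin gene HBZ (-2.16), RHOB (-2.08) and the plasma membrane calcium pump ATP2B4 (-2.05). PLEKHO2, HBZ and ATP2B4 each had 1 E2F-1 array at the floor, and differed by -2.93, -2.18 and -2.53 with the floor at the 5th percentile. With it at the 40th both E2F-1 arrays were at the floor for these genes and for RNF41. PLEKHO2, HBZ, ATP2B4 and RNF41 were then lower by at least 1.41, 0.998, 1.22 and 1.53. RNF41 was 9.65-fold lower in repeat 1 and 2.20-fold lower in repeat 2. ATP2B4 differed by -1.26 without the E2F-1 array of repeat 1, and RAPGEF3 by -1.63 without LacZ of repeat 1. ATP2B4 alone of the 12 did not pass the blocked test (adjusted p = 0.0604), and a dim ATP2B4 probe set, at the floor in both arrays of repeat 2, had the opposite sign in repeat 1 (0.85). None of the 12 passed without the block.

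**Figure D2:**
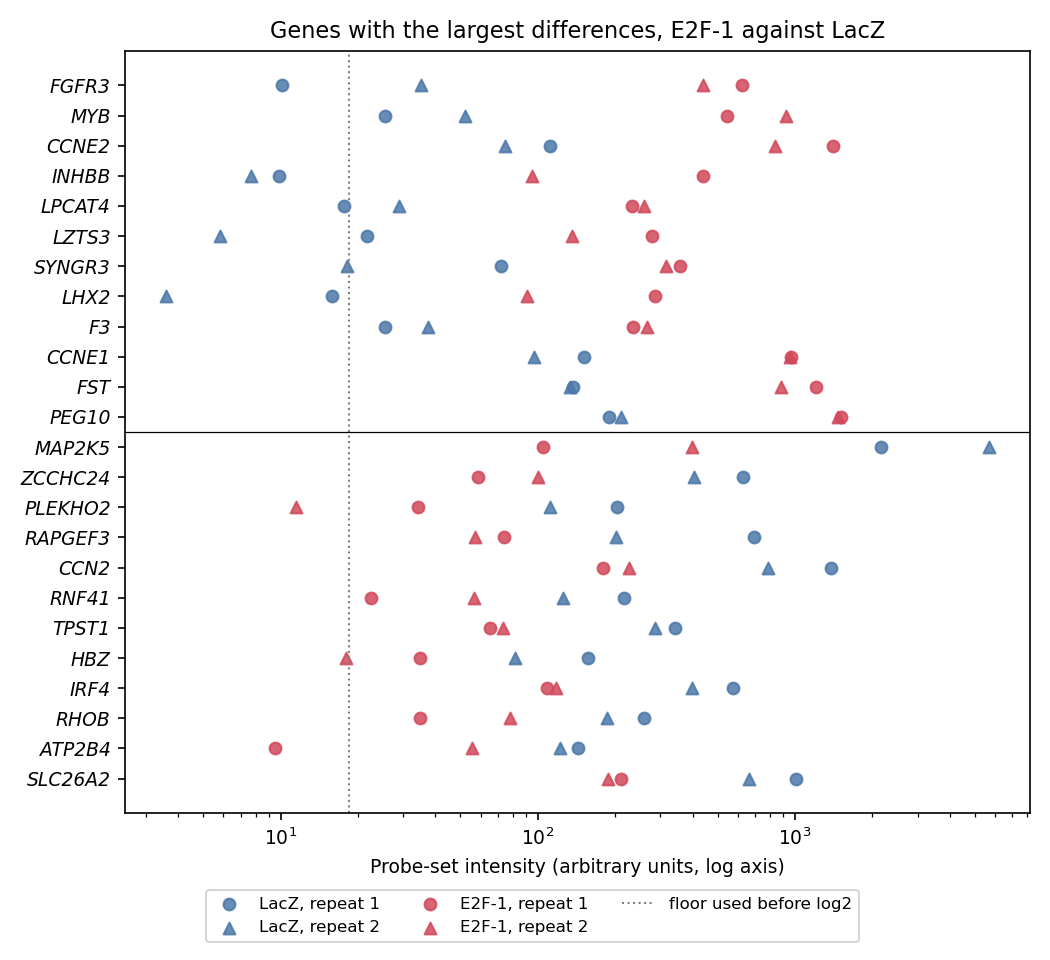
Intensity (arbitrary units, log axis) of the 12 genes with the largest positive and the 12 with the largest negative differences on each of the 4 arrays, blue for LacZ, red for E2F-1, circles for repeat 1 and triangles for repeat 2. The dotted line is the floor of 18.4, and both LacZ points of INHBB and LHX2 lie to its left.

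MAP3K5, which encodes ASK-1, a kinase that activates JNK and p38 under stress, read 70.3 and 57.0 in the LacZ arrays against 620 and 234 in the E2F-1 arrays. The difference was 2.59 ± 0.57, or 8.82-fold in repeat 1 and 4.10-fold in repeat 2. It did not pass limma without the block (adjusted p = 0.525) and passed with it (adjusted p = 0.00428).

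Genes of G1/S and DNA replication stood higher with E2F-1 as a list, with a median difference of 0.31 over 43 measured genes, 0.21 in repeat 1 and 0.32 in repeat 2 (camera adjusted p = 0.0013, 0.00193 with the block, and adjusted p = 0.572 with an estimated correlation). The list was not called by fry (adjusted p = 0.315, and 0.234 with the block). Of the 43, 24 were higher and 7 lower in both repeats, against 31.9% and 37.6% of all genes. In the blocked test 6 passed as higher and 0 as lower (10 and 0 adjusted over the list alone), and without the block 0 passed (3 adjusted over the list alone). CCNE2 and CCNE1 led, followed by RRM2, a subunit of ribonucleotide reductase, at 179 and 519 against 911 and 2425 (2.28 ± 0.70, and 1.52 without the LacZ array of repeat 1), and SLBP, which binds histone mRNA, at 451 and 428 against 1570 and 1210 (1.65 ± 0.31). The others past the blocked test were CCND3 (1.48) and CDC25A (1.02). Without the E2F-1 array of repeat 2 the list was no longer called (median 0.18, camera adjusted p = 0.11), and its median was 0.18 without LacZ of repeat 1 and 0.50 without E2F-1 of repeat 1.

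The list of CDK inhibitors, RB family members and G1 cyclins was likewise higher, with a median of 0.43 over 18 genes, 0.53 in repeat 1 and 0.24 in repeat 2 (camera adjusted p = 0.00368, 0.00773 with the block, and adjusted p = 0.774 with an estimated correlation). Fry did not call the list (adjusted p = 0.315, and 0.124 with the block). In the blocked test 6 passed as higher and 0 as lower (7 and 2 adjusted over the list alone), and without the block 0 passed (2 adjusted over the list alone). The members that passed were mostly inhibitors of cyclin-dependent kinases. CDKN1A, which encodes p21, read 187 and 158 against 1111 and 1046 (2.65 ± 0.29), and CDKN1B, which encodes p27, read 113 and 107 against 755 and 405 (2.33 ± 0.41). CDKN2A differed by 1.39 ± 0.41, CDKN2D by 0.98 ± 0.33, CDKN1C by 0.98 and CCND3 by 1.48. The list's median was 0.16 with no filter on dim probe sets, 0.71 without the LacZ array of repeat 2 and 0.75 without E2F-1 of repeat 2, and it was called in each case.

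Of 31 measured genes of G2/M and mitosis, 0 passed in either direction, 12 were higher and 14 lower in both repeats, and the list was not called (camera adjusted p = 0.726). Its median was -0.03 while its mean and camera's direction were above 0. The members with the smallest p differed by 0.57 (KIF11), -0.69 (TTK), 0.62 (CDK1) and 0.66 (ZWINT). With 1 array left out the smallest values were 0.37, -0.41 and 0.26 for the first 3, and the list's median reached 0.24.

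Melanocyte lineage genes stood lower with E2F-1, with a median of -0.43 over 19 genes, -0.36 in repeat 1 and -0.39 in repeat 2 (camera adjusted p = 0.00177, 0.00404 with the block, and adjusted p = 0.572 with an estimated correlation). Fry called the list as lower (adjusted p = 0.0296, and 0.0318 with the block). Of the 19, 14 were lower and 1 higher in both repeats. In the blocked test 4 passed as lower and 0 as higher, with the same counts adjusted over the list alone, and without the block 0 passed either way. These were MITF, the master transcription factor of melanocytes, at 1050 and 1191 against 414 and 500 (-1.30 ± 0.30), its regulator SOX10 (-1.19 ± 0.32), the melanocortin receptor MC1R (-1.53 ± 0.52), and ERBB3, at 1982 and 1743 against 712 and 591 (-1.52 ± 0.31). Of 6 dimmer ERBB3 probe sets, 3 differed by -1.67 to -1.46 and 3 by only -0.50, -0.23 and -0.09. TYR (-0.64), MLANA (-0.37) and PMEL (-0.29), chosen after their values were seen, did not pass. Without the LacZ array of repeat 2 the list was not called (camera adjusted p = 0.0534).

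Cancer-testis antigens, germ-cell genes often expressed in melanoma, were lower as well, with a median of -0.69 over 9 genes, -0.80 in repeat 1 and -0.63 in repeat 2 (camera adjusted p = 0.00368, 0.00293 with the block, and adjusted p = 0.572 with an estimated correlation). Fry did not call this list (adjusted p = 0.391, and 0.234 with the block). In the blocked test 3 passed as lower and 0 as higher (5 and 0 adjusted over the list alone), and without the block 0 passed either way. MAGEB1 differed by -1.30 ± 0.41, MAGEA12 by -1.02 ± 0.58 and MAGEB2 by -0.85, while PRAME (-0.96 ± 0.39, blocked adjusted p = 0.0523) and SSX1 (-0.56 ± 0.30) did not pass. In the blocked fit the SE was 0.18 for MAGEA12 and 0.25 for PRAME. With 1 array left out MAGEA12 ranged from -1.61 to -0.43, and PRAME came to -0.64 without E2F-1 of repeat 1. MAGE and SSX genes have near-identical relatives, so which member of a family was measured is uncertain. Without the E2F-1 array of repeat 2 the list was not called (median -0.45, camera adjusted p = 0.0877).

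**Figure D3:**
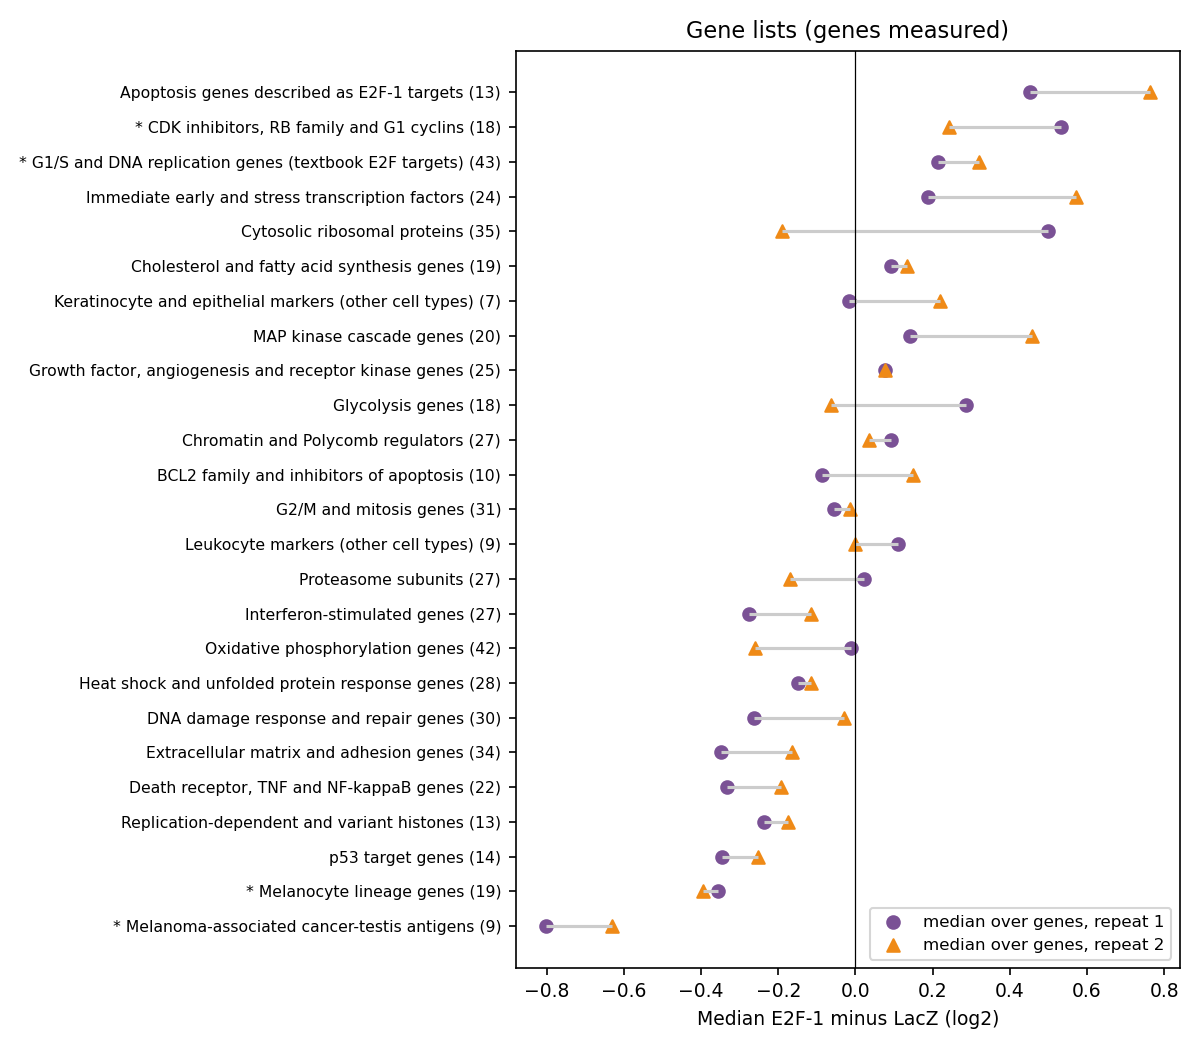
Median E2F-1 minus LacZ difference (log2) over the measured genes of each of the 25 lists tested, with a circle for repeat 1 and a triangle for repeat 2 joined by a line. Asterisks mark the 4 lists past the camera threshold, 2 higher and 2 lower, and the ribosomal protein list is the one whose medians lie farthest apart on both sides of 0, at 0.50 and -0.19.

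Apoptosis genes described as E2F-1 targets had a median of 0.65 over 13 genes and were not called as a list (camera adjusted p = 0.169). The median was 0.08 with no filter on dim probe sets and 0.25 without the LacZ array of repeat 2, and without LacZ of repeat 1 it was 1.05 and the list was called (camera adjusted p = 0.037). In the blocked test 4 passed as higher, MAP3K5, HRK (1.67), CDKN2A and BID (0.84), and 1 as lower, the initiator caspase CASP8 (-1.08 ± 0.35), 1 dim probe set of which had the opposite sign (0.19). Adjusted over the list alone these counts were 7 and 3, and without the block 0 passed. BCL2L11, which encodes the pro-apoptotic protein BIM, read 44.8 and 37.9 against 151 and 107 (1.63 ± 0.58) and did not pass (blocked adjusted p = 0.0527). In the list of the BCL2 family and inhibitors of apoptosis, 1 of 10 passed the blocked test, BCL2 itself (1.87), and the list was not called (camera adjusted p = 0.533). Of 22 death receptor, TNF and NF-kappaB genes, TNFRSF1A (-1.19) and TRAF1 (-1.05) passed as lower (camera adjusted p = 0.169). Of 14 p53 target genes, CDKN1A passed as higher, and CCNG1 (-1.12) and PLK2 (-1.50) as lower (camera adjusted p = 0.539).

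Among 20 MAP kinase cascade genes, MAP3K5 and the phosphatases DUSP7 (1.94 ± 0.48) and DUSP5 (0.98) passed the blocked test as higher, and MAP2K5 and DUSP6 (-1.36 ± 0.36) as lower (camera adjusted p = 0.277, and 0.038, higher, without the E2F-1 array of repeat 1). The median of this list was 0.14, and with 1 array left out ranged from -0.08 to 0.53. Among 24 immediate early and stress transcription factors, 5 passed as higher and 3 as lower (camera adjusted p = 0.0702, and 0.000389, higher, without the LacZ array of repeat 1). Their median was 0.90 without that array and 0.02 without E2F-1 of repeat 1. KLF10 read 230 and 241 against 1281 and 1176 (2.38 ± 0.28), JUND differed by 1.18 ± 0.32, CEBPD by 1.69 ± 0.49, GADD45B by 1.57 and NR4A2 by 2.08, whereas KLF6 differed by -1.10 ± 0.33, EGR3 by -1.69 and IER3 by -0.79. Of 27 chromatin and Polycomb regulators, 3 passed as higher and 0 as lower (camera adjusted p = 0.277, and 0.038, higher, without the E2F-1 array of repeat 1). The list's median was 0.07, and -0.03 without LacZ of repeat 1. EZH2, a histone H3 methyltransferase, read 500 and 846 against 2292 and 3881 (2.20 ± 0.46), EED differed by 0.90 ± 0.35 and SUZ12 by 0.94 ± 0.51, which ranged from 0.38 to 1.5 with 1 array left out. The remodeller SMARCA2 (0.71 ± 0.28) did not pass (blocked adjusted p = 0.0503).

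Among 25 growth factor, angiogenesis and receptor kinase genes, FGFR3 and PDGFA (1.94) passed the blocked test as higher, and CCN2, ERBB3 and TGFBR2 (-1.60) as lower (camera adjusted p = 0.744). Of 34 extracellular matrix and adhesion genes, PLAT (-0.94) and TGFBI (-0.75) passed the blocked test as lower, 6 did so adjusted over the list alone, and 18 were lower and 5 higher in both repeats. The list was not called by camera (adjusted p = 0.183), but was called as lower by fry with the block (adjusted p = 0.0318) and by camera without the LacZ array of repeat 1 (adjusted p = 0.037). Of 27 interferon-stimulated genes, IRF1 passed as higher (2.55) and IFI16 as lower (-1.30), and the list was not called (camera adjusted p = 0.662). Glycolysis genes had ENO2 (1.60) higher and SLC2A3 (-1.05) lower among 18 (camera adjusted p = 0.823, and 0.00188, higher, without the LacZ array of repeat 2, with a median from -0.48 to 0.43 over the fits with 1 array left out), and cholesterol and fatty acid synthesis genes had INSIG1 (1.21) higher and MSMO1 (-0.92) lower among 19 (camera adjusted p = 0.488). Each list of this paragraph and the 2 before it had an adjusted p of at least 0.774 with an estimated correlation.

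In 5 lists of other housekeeping and repair functions 0 genes passed in either direction and the list was not called with all 4 arrays. These were 28 heat shock and unfolded protein response genes (median -0.16, camera adjusted p = 0.488, and 0.0427, lower, without the LacZ array of repeat 1), 13 histones (-0.28, 0.419), 30 DNA damage response and repair genes (-0.18, 0.641), 42 oxidative phosphorylation genes (-0.14, 0.419) and 27 proteasome subunits (-0.07, 0.488). With 1 array left out the medians of the first 4 reached 0.12, 0.04, 0.08 and 0.08, so their sign is open, and that of the last was as low as -0.22. The 35 ribosomal protein genes, among the brightest on the arrays, had a median of 0.50 in repeat 1 and -0.19 in repeat 2, and 0 passed (camera adjusted p = 0.44). This list was called as lower without the LacZ array of repeat 1 (median -0.91, adjusted p = 4.09e-08), and as higher without LacZ of repeat 2 (1.13, adjusted p = 1.45e-23) and without E2F-1 of repeat 1 (0.86, adjusted p = 3.45e-05). These calls rest on the preset correlation, whereas the estimated one was 0.967 for this list and gave an adjusted p of 0.905 with all arrays. Of the markers of other cell types, 0 of 7 keratinocyte and epithelial ones passed (camera adjusted p = 0.641), 0 of 9 leukocyte markers (camera adjusted p = 0.823, median -0.04, or -0.46 to 0.51 with 1 array left out), and 0 of 3 fibroblast and smooth muscle markers, too few for the list test. Each list tested in this paragraph had an adjusted p of at least 0.814 with an estimated correlation.

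Bright probe sets read lower on both repeat 1 arrays. The GAPDH control probe set for the 3' end read 151 and 291 in repeat 1 (LacZ and E2F-1) and 14220 and 12890 in repeat 2, and that for Alu repeats read 104 and 291 against 15841 and 15598. Over the 8 brightest probe sets of repeat 2 the median of repeat 1 minus repeat 2 was -6.32, and over the 90 next brightest, all at 6400 or more, it was -2.05. The control probe set for the 3' end of 18S rRNA went the other way, at 662 and 521 in repeat 1 against 60 and 28.5 in repeat 2. The loss met both groups of repeat 1, but unequally. The actin control probe set for the 3' end read 928.8 (LacZ) and 3266 (E2F-1) in repeat 1 against 11700 and 11596 in repeat 2. The bacterial CreX-3 read 1835 and 3941 in repeat 1, and the dim BioB-3 was unequal as well, at 366 and 724. The other Bio and CreX control probe sets also read higher in E2F-1 of repeat 1, such as BioC-3 at 402 and 676. In repeat 2 they went both ways, with BioC-3 at 773 and 738 and BioB-M at 612 and 724. Group differences in repeat 1 may hold part of this inequality, for bright genes such as the ribosomal ones and for dimmer genes as well. MAP2K5, EZH2 and all 35 ribosomal protein genes reached 3200 or more on a repeat 2 array. The 237 probe sets with a geometric mean of at least 3200 over both repeat 2 arrays were left out in an alternative. MAP2K5 (5660 and 399 in repeat 2, LacZ and E2F-1) and EZH2 (846 and 3881) were under that mean and stayed in. The blocked counts were then 387 and 280, and 2 lists were higher and 2 lower. The 2-fold counts stayed at 161 and 60 because none of these probe sets was among those left out. The unchanged counts therefore say nothing about bright genes that differ.

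**Figure D4:**
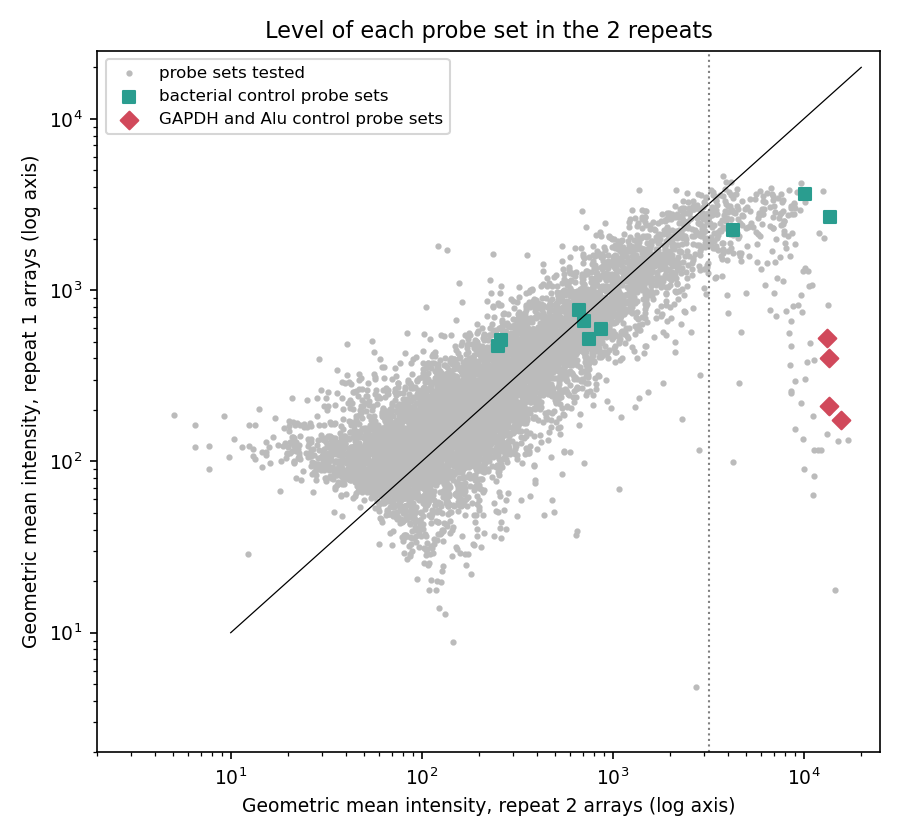
Geometric mean intensity of each probe set over the 2 arrays of repeat 1 (vertical, log axis) and of repeat 2 (horizontal, log axis), in arbitrary units, with the line of equality and a dotted line at 3200. Bacterial control probe sets (squares) bend away from equality at the bright end, and the GAPDH and Alu controls (diamonds) lie far below it, as with 14220 in repeat 2 and 151 in repeat 1 for LacZ.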

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

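Alternatives named here as combined with the block, repeats used alone and the omission of bright probe sets were chosen after seeing the data. The labels give same-numbered arrays no shared source. Their values group by number, with Pearson correlations (log2) of 0.85 within repeat 1 and 0.93 within repeat 2. Arrays of different repeats correlated at 0.75 to 0.81. What same-numbered arrays shared remains unknown. The repeat differences of the LacZ and of the E2F-1 arrays correlated at 0.75 across probe sets. With the replicate block, limma called 360 probe sets higher and 258 lower in place of 0 and 0. At an adjusted p under 0.10 without the block it called 0 and 0. With the block, quantile normalization gave 197 and 74, a floor at the 40th percentile gave 392 lower, and no filter or no intensity trend gave 0 and 0; the cause was not tested. Without the block, the scaling, floor, filter and trend alternatives all left 0 and 0.

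Leaving out 1 array gave 0 to 9 probe sets higher and 0 to 1 lower, with the lone array of a group taken to vary like the others. The E2F1 difference lay between -0.165 (without LacZ replicate 2, the only reversal) and 0.292. The 2-fold counts lay between 245 and 446 higher and between 124 and 402 lower, since fewer comparisons had to hold. Lists called numbered 1 to 5 higher and 1 to 5 lower, the ribosomal list among the lower without LacZ replicate 1 and among the higher without LacZ replicate 2 or E2F-1 replicate 1. No test of the blocked fit was possible with an array left out, for want of residual degrees of freedom.

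The count of 60 lower became 96 with no filter and 32 with a filter at the 60th percentile, since these test more and fewer probe sets. At 1.5-fold the counts were 337 and 253. Under the replicate block as 2-fold within both pairs they were 264 and 148, in repeat 2 alone 546 and 307, and in repeat 1 alone 606 and 693, again with fewer comparisons to meet. Of the 2 lists higher and 2 lower, camera with an estimated correlation called 0 and 0, and fry 0 and 1 (with the block 2 lists, the melanocyte and the extracellular matrix list). The estimated correlations were 0.013 for the G1/S list, 0.125 for the CDK inhibitor list, -0.049 for the melanocyte list and -0.054 for the cancer-testis list. With 2 residual degrees of freedom that form of camera could hardly call a list. Its lack of calls therefore does not tell whether correlation between genes accounts for these lists. The same 4 lists were called under each scaling, floor, filter, trend and block alternative, and the immediate early list joined them with median scaling and with no filter. Of 698 values of the 55 named genes other than E2F1 under alternatives, 643 kept their side of the threshold, 55 passed it (under the block or with an array left out), 0 were reversed, and 17 were missing because the filter had removed the probe set. The genes with the largest differences were chosen as 2-fold apart in every comparison, so leaving out 1 array could not reverse them. As 0 genes passed the main test, keeping a side of the threshold means not passing there either. This tally therefore says little about how stable the named genes are. Quantile normalization, median scaling and no scaling moved the median of all probe sets by under 0.1. No detection calls show how far a reading stood over background, so dim probe sets are limited by the choice of the floor.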

Other observations

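Of the tests in this part, those on the bright probe sets, on MAP2K5 and on E2F1 were chosen only after the result was seen. The genes of the next paragraph were chosen after their values were seen, so they stand as values.

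Values of 5 genes outside the lists follow, and they stand for no group. The ligand BMP2 was at the floor in both LacZ arrays and read 191 and 80.5 with E2F-1. The inhibitory SMAD6 read 50.2 and 85.9 in the LacZ arrays against 244 and 404 (log2 difference 2.26 ± 0.50, SE, 2 arrays per group). SMAD1, which transmits BMP signals, read 65.7 and 103 against 218 and 408 (1.85 ± 0.50). The activin receptor ACVR1B read 455 and 297 against 1628 and 947 (1.76 ± 0.42), although 4 other ACVR1B probe sets differed by 0.40 to 1.43. CXADR, the cell-surface receptor that many adenoviruses bind, read 372 and 427 against 997 and 1164 (1.44 ± 0.30). These probe sets passed limma with the repeat as a block, with adjusted p of 0.0328 (BMP2), 0.00374 (SMAD6), 0.00605 (SMAD1), 0.00233 (ACVR1B) and 0.00428 (CXADR), and did not pass without it.

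Homeobox genes were seen among the largest positive differences, and the hypothesis was that they may stand higher as a class. Among the 44 measured genes with homeobox name prefixes, other than 4 already seen, 5 passed the blocked test as higher, against 4.87% of other genes, an odds ratio of 2.50 (one-sided Fisher exact p = 0.0633), so the hypothesis stays open. The 4 left out were LHX2, IRX5, HOXD8 and DLX2. The probe set that represents DLX2 differed by only 0.09 and did not pass (blocked adjusted p = 0.854). Leaving DLX2 out, here and in the step below, could only raise the odds ratio. The prefixes had also matched 4 names that are pseudogenes or carry no homeobox. Without them, a step chosen after the result, 5 of 40 passed (odds ratio 2.79, one-sided Fisher exact p = 0.045). The 8 that passed with those already seen included were LHX2, HOXD8 (2.57), IRX5 (2.04), CUX1 (1.26), HOXD4 (1.18), MSX1 (1.14), PBX3 (0.96) and HOXB7 (0.76), while TGIF1 passed as lower (-0.94), and another CUX1 probe set had the opposite sign (-1.45).

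The loss of bright signal in repeat 1 reached the bacterial control probe sets, whose RNA does not come from the cells. The 3 that exceeded 3200 in repeat 2 had a median of repeat 1 minus repeat 2 of -1.48 (log2), against 0.06 for the 6 dimmer ones. Less or degraded cell RNA as the whole cause would keep the ratio of bacterial controls, but CreX-3 over BioB-3 was 5.02 and 5.45 in repeat 1 and 48.1 and 58.2 in repeat 2, 10.1 times as high. A candidate explanation is saturation of bright probes in repeat 1. Whether saturation could take the brightest probe sets to a median difference of -6.32 was not tested, since values of single probes were not used. No biological explanation was tested, since both groups of repeat 1 show the loss.

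The brightest MAP2K5 probe set was lower with E2F-1 in both repeats, but a loss of all MAP2K5 transcripts would lower the gene's other probe sets too. Their median difference was -0.186, with none below -0.40. They read under 2 times the median of their array in LacZ, so they may not detect the transcript, and this leaves a loss of all forms open. A change in 1 transcript form and cross-hybridisation with RNA of the LacZ vector were not tested, since probe sequences were not used here.

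The E2F1 probe sets were near their LacZ level in the cells given E2F-1, while the cyclin E genes stood 7.97-fold (CCNE1) and 11.9-fold (CCNE2) higher. Titles exchanged within 1 pair would turn the differences of the repeats against each other, yet these correlated at 0.535 across probe sets. An exchange in both pairs would leave this correlation unchanged and was not tested. The highest E2F1 difference was 0.593. E2F1 probes outside the sequence carried by the vector may explain this and remain open, because the insert and the probe positions are not given in the sources used here.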
